A study of Gallus gallus with 6 samples.

How the data were processed

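Total RNA from chicken feather follicle parts was sequenced with standard Illumina protocols, with 1 library for each of 6 groups, which were taken from the sample labels. Per the file headers each table gave a gene expression column, which the authors deposited as whole-number counts per RefSeq transcript record; no value under 2 was listed. A further column, headed TPM, was not divided by transcript length: the deposited value was in RPM, the count scaled to a library total larger than the sum of the listed counts. That total was recovered from records with at least 500 counts, and the listed counts made up 40.0% to 44.5% of it. Per the submitters' processing notes the genome build was mm10, a mouse build, although the records are chicken transcripts; the aligner, the counting method and the strand are not given in the sources used here. The epithelium and pulp tables had a different text layout from the other 4.

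The tables held 10964 records in at least 1 library and 7058 in all 6. Of the 10964, 4821 carried a gene symbol in the tables, 5008 were named through their gene identifier and 10 through their accession in a RefSeq gene table, and 1125 kept a LOC number or had no name. The 48 symbols with at least 2 records were kept as separate records, and in lists the record with the most reads stood for its gene. Library totals ranged from 3269376 to 6064791. Scaling factors by the trimmed mean of M values (TMM) were computed with edgeR 4.0.16 in R 4.3.3 over the 6 libraries on the recovered totals: 0.997 for the growth-phase papilla, 0.688 for the epithelium, 1.02 for the pulp, 1.09 for the resting papilla, 1.12 for day 2 and 1.17 for day 4. The 10 most abundant records took 28.6% of listed counts in the epithelium and 9.56% to 16.1% in the other libraries.

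Log2 ratios used TMM-scaled CPM plus a pseudocount of 1, among records with at least 20 reads in at least 1 library of the pair, and a record was counted as higher or lower at 2-fold. No test across genes was made, since each group had 1 library. Records enriched in the papilla were at least 4-fold higher than in both the epithelium and the pulp. Printed folds of single genes are ratios of scaled counts with no pseudocount, with exact conditional binomial (Clopper-Pearson) 95% intervals for 2 Poisson counts. The number of records 2-fold apart from counting error alone was the mean of 20 simulations.

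The 32 gene lists, the comparisons, the rule for named genes and all alternatives except those said to be added were fixed before the data were examined. The lists covered dermal papilla, epithelium, feather cornification, fibroblast and matrix, basement membrane, endothelium, smooth muscle, skeletal muscle, melanocyte, nerve, leukocyte, erythroid, adipocyte, cartilage and tendon, Wnt ligands, Wnt inhibitors, Wnt receptors and targets, BMP and TGF-beta, FGF, hedgehog with Notch and EDA, retinoic acid, proliferation, growth arrest, wound and inflammation, matrix remodelling, immediate early and stress, hypoxia and glycolysis, oxidative phosphorylation, ribosomal protein, homeobox and T-box, adhesion and guidance, and housekeeping genes. A list with at least 3 measured members was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, and stood apart under percentile 2.5 or over percentile 97.5.

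Genes were named by rule: per comparison the 6 highest and 6 lowest log2 ratios among records with a symbol and at least 200 reads in the higher library, up to 4 members of each described list by absolute ratio, the 12 enriched records with the largest smaller ratio, and 14 signalling and marker genes in every comparison, of which FGF10 was not matched to a record. CHCHD2 reads in all libraries and records outside this rule in the closing part were chosen after their values were seen.

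The procedure was tested on simulated Poisson counts, in which 200 records with at least 20 expected reads in both libraries were altered, equally up and down. All of the 4-fold differences and 89.0% to 97.0% of the 2.83-fold differences were recovered, and 0.172% to 0.353% of unaltered records were called. Differences in composition as large as those between these tissues, and spread between birds, were not simulated, so these shares hold for the simulated setting only. The 95% intervals covered the true ratio in 95.4% to 96.0% of cases, and 2 to 5 of 100 random lists stood apart per comparison. The 13 alternatives were median-of-ratios scaling, upper-quartile scaling, scaling without the 100 most abundant records, pseudocounts of 0.1 and 5, no filter on low counts, a minimum of 200 reads, a 4-fold size rule, the mean of list members, records summed per symbol and, chosen after seeing the data, the deposited RPM values, an enriched list also 2-fold above the day 4 follicle and an enriched list chosen in the resting papilla. No library was left out. Coordinates were not used. Further computation and plotting used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.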

Results

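Gene expression was measured by sequencing libraries of total RNA from parts of the chicken feather follicle. 3 libraries came from the growth phase: the dermal papilla, a cluster of mesenchymal cells at the follicle base, the feather epithelium, and the mesenchymal pulp that fills the growing feather. 1 library came from the dermal papilla at the resting phase, and 2 came from the regeneration phase, 2 and 4 days after wounding. The day 2 label names the feather follicle, while the day 4 label names no tissue. Calling the day 4 library a follicle is therefore an assumption. Each of the 6 groups had 1 library, so no difference reported here has a replicate check. The tables gave whole-number counts per RefSeq transcript record and listed only records with at least 2 counts. A record that a table does not list was taken to hold 0 or 1 counts, and on that assumption its fold is a bound taken at 3 counts in that library. The listed counts summed to 1425395 in the growth-phase papilla, 2428052 in the epithelium, 2364748 in the pulp, 1393419 in the resting papilla, 1375518 in the day 2 follicle and 1499592 in the day 4 follicle. Ratios of single genes carry exact 95% intervals, which cover counting error only. List percentiles refer to 10000 random lists of matched size and expression and describe these libraries.

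The epithelium and pulp libraries were deeper than the other 4 (library totals of 6064791 and 5683214 against 3269376 to 3410046), and their tables had another text format. Comparisons of the papilla with epithelium or pulp therefore also compare these sets of tables. In 59 records both libraries lay at least 4-fold above (29) or below (30) each of the other 4; they included CHCHD2 and DRAXIN, above, and MUSTN1, DES, MYLK, MYH11, LRRN6A, HSPB1 and COMP, below. Across 7205 records with at least 20 reads in some library, the highest rank correlation of expression was between the day 2 and day 4 follicles (Spearman 0.946). The resting papilla followed, with the day 2 follicle (0.916) and with the day 4 follicle (0.914). The lowest was between epithelium and pulp (0.599). The papillae of both phases correlated at 0.910, below the values of the resting papilla with either follicle. Genes are not independent replicates, so these values only rank the similarity of the libraries.

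**Figure D1:**
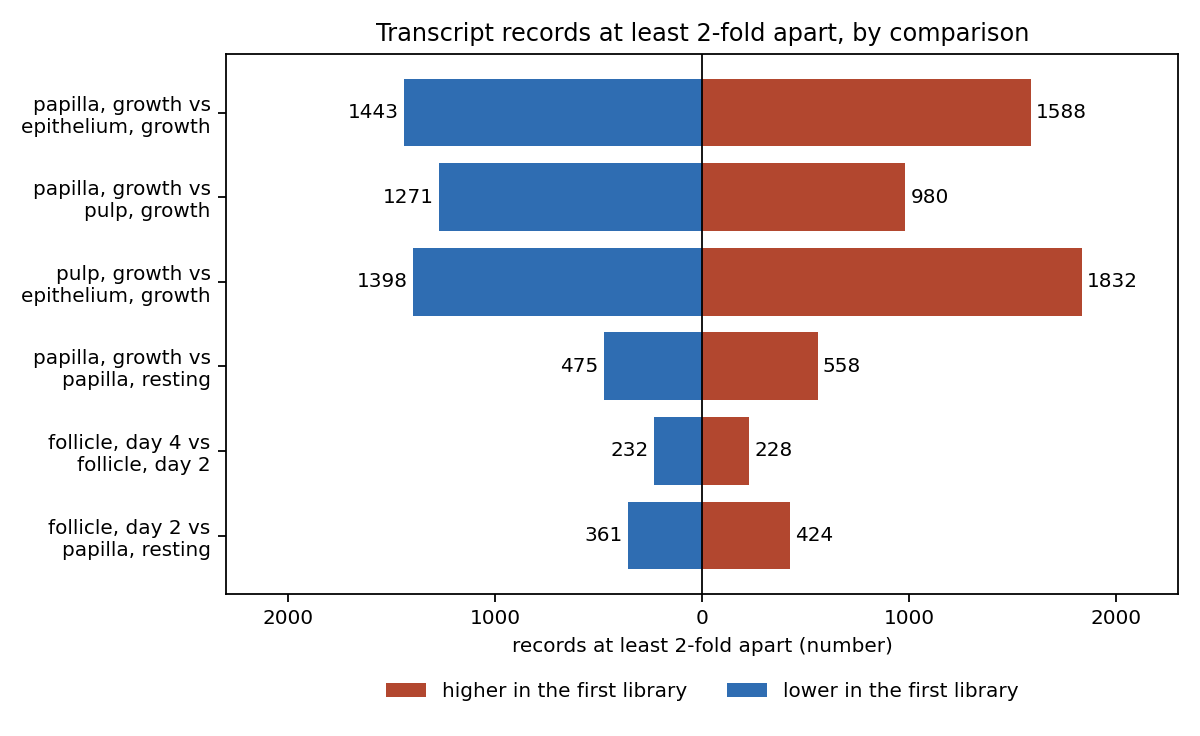
Number of transcript records at least 2-fold higher (red, to the right) or lower (blue, to the left) in the first library than in the second, for each of the 6 comparisons; the horizontal axis is a count of records. The bars run from 228 higher and 232 lower between the follicles of day 4 and day 2 to 1832 higher and 1398 lower between pulp and epithelium.

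The growth-phase papilla was first set against the growth-phase epithelium, which asks how the mesenchymal signalling centre differs from the tissue that forms the feather. The Wnt inhibitors FRZB, SFRP2 and DKK2 and the growth factor BMP4 were higher in the papilla: FRZB by 149-fold (98.4 to 239), SFRP2 by 199-fold (54.6 to 1649), DKK2 by 60.1-fold (36.8 to 106) and BMP4 by 119-fold (62.6 to 262). Desmin (DES, LOC395906 in the tables), a muscle intermediate filament, had 1162 reads in the papilla and was unlisted in the epithelium, at least 475-fold higher. CSRP1, a LIM-domain protein of smooth muscle, was 262-fold (235 to 292) higher, the focal adhesion protein TNS1 288-fold (177 to 504), MUSTN1 235-fold (185 to 305), the desmin-binding filament protein DMN 573-fold (158 to 4735) and the secreted protease-inhibitor-domain protein WFIKKN2 522-fold (204 to 1919).

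Lower in the papilla were CSTA (LOC418268), a protease inhibitor of the cornified envelope, by 2035-fold (1253 to 3560.0), and the fatty acid binding protein FABP5 by 355-fold (293 to 433). LY6EL was 225-fold (129 to 436) lower and E-cadherin (CDH1) 8.61-fold (6.87 to 10.9) lower. The pigment cell genes TYRP1 and MLANA, with 1151 and 872 reads in the epithelium, were unlisted in the papilla and at least 313-fold and at least 237-fold lower. The keratin KRT75L2 was at least 152-fold lower; keratin genes have near-identical copies, so reads of such records are uncertain. Sonic hedgehog (SHH) was listed in the epithelium alone among the 6 libraries, with 48 reads (at least 13-fold lower in the papilla), and the Wnt effector LEF1 was 28.2-fold (11.9 to 87.9) lower in the papilla.

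Among the gene lists, 26 of 27 measured fibroblast and matrix genes were at least 2-fold higher in the papilla and 0 lower (median log2 ratio 4.49, percentile 100). The mesenchymal transcription factor PRRX1 was 393-fold (108 to 3250.0) higher and the collagen COL1A2 57.9-fold (50.4 to 66.8). Of 18 dermal papilla markers, 15 were higher and 1 lower (median log2 ratio 3.74, percentile 100); LEF1 was the lower member. The smooth muscle list had 12 of 13 members higher (median log2 ratio 6.00, percentile 100), with TAGLN at 192-fold and MYL9 at 189-fold. The endothelium list had 15 of 15 higher (median log2 ratio 3.64, percentile 100) and the leukocyte list 10 of 10 (median log2 ratio 2.35, percentile 99.96), so blood vessel and immune cell markers were higher together with the mesenchymal genes. The epithelium list had 13 of 19 members lower (1 higher, median log2 ratio -2.53, percentile 0), the feather cornification list 7 of 9 (median log2 ratio -3.61, percentile 0) and the melanocyte list 7 of 7 (median log2 ratio -6.39, percentile 0).

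Signalling and growth lists also stood apart. Of 10 Wnt inhibitors, 6 were higher and 4 lower in the papilla (median log2 ratio 3.42, percentile 100), and DRAXIN was the lower member with the largest ratio, 20.6-fold (7.79 to 77.0). The BMP and TGF-beta list had 14 of 22 higher (1 lower, median log2 ratio 1.88, percentile 99.99), led after BMP4 by the latent TGF-beta binding protein LTBP1 at 67.7-fold (47.2 to 101). Basement membrane genes were higher in 12 of 16 (median log2 ratio 1.84, percentile 99.97) and matrix remodelling genes in 7 of 14 (4 lower, median log2 ratio 1.09, percentile 98.9). Proliferation genes were lower in 16 of 30 (median log2 ratio -1.04, percentile 0.0100): TOP2A, a DNA topoisomerase of dividing cells, was 3.63-fold (2.68 to 4.98) lower, while MKI67 differed by a ratio of 1.07 (0.758 to 1.5). Ribosomal protein genes, which have many near-identical copies, were lower in 34 of 52 (median log2 ratio -1.45, percentile 0). The skeletal muscle list rested on 4 measured genes (median log2 ratio 3.07, percentile 99.7).

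In total 1588 records were at least 2-fold higher and 1443 lower in the papilla than in the epithelium, of 6362 with at least 20 reads in either library; counting error alone gave 20.3 on average in simulations. With the RPM values as deposited, an alternative chosen after seeing the data, the median log2 ratio of all records was 0.45 in place of -0.05 and the split became 2231 higher and 861 lower; at a minimum of 200 reads it turned to 459 higher and 541 lower. The proliferation and matrix remodelling lists no longer stood apart at a minimum of 200 reads, nor the skeletal muscle list with no filter on low counts.

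The growth-phase papilla was next set against the growth-phase pulp, which lies directly above it. OSTN, which encodes the secreted peptide osteocrin, was 431-fold (226 to 943) higher in the papilla, MUSTN1 274-fold (219.8 to 346), WFIKKN2 416-fold (201 to 1036), smooth muscle myosin MYH11 127-fold (108 to 150.0), DES 153-fold (89.1 to 288) and the small heat shock protein HSPB7 (LOC430280) 163-fold (91.0 to 328). DKK2 was 8.64-fold (7.26 to 10.3) higher in the papilla, whereas FRZB was 1.28-fold (1.22 to 1.34) higher and BMP4 1.83-fold (1.66 to 2.01) higher. SFRP2 went the other way and was 3.55-fold (3.15 to 4.00) lower in the papilla, as was LEF1, by 25.8-fold (10.9 to 80.4).

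CRABP1 and ALDH1A3 were lower in the papilla than in the pulp: CRABP1, which binds retinoic acid in cells, by 103-fold (78.3 to 139), and ALDH1A3, an enzyme of its synthesis, by 84.1-fold (35.9 to 259.7). The retinoic acid list as a whole did not stand apart, with 3 of 7 lower and 4 within 2-fold (median log2 ratio -0.59, percentile 15.2). The chemokine CCL26 (LOC417534), with 1003 reads in the pulp, was unlisted in the papilla and at least 195-fold lower. The BMP family member GDF10 (LOC423776) was 43.0-fold (27.5 to 71.7) lower and EGFL6 53.2-fold (25.7 to 133). CHCHD2 was 58.2-fold (35.7 to 102) lower, and it was also low in the other 3 libraries that share the papilla's table format, with 10 to 25 reads, against 1130 in the epithelium.

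The smooth muscle list had 11 of 14 members higher in the papilla and 1 lower (median log2 ratio 4.40, percentile 100); the pericyte receptor PDGFRB was the lower one, by 6.15-fold (4.62 to 8.34). Endothelial markers did not follow it: 1 of 19 was higher and 5 were lower (median log2 ratio -0.83, percentile 1.12). Leukocyte markers were lower in 21 of 23 (median log2 ratio -2.11, percentile 0), with the complement gene C1QB 26.9-fold (19.4 to 38.6) lower, and wound and inflammation genes in 10 of 20 (median log2 ratio -0.99, percentile 0.280), with the chemokine CXCL14 23.7-fold (21.5 to 26.1) lower. The erythroid list had 3 of 6 lower (median log2 ratio -1.39, percentile 0.590); haemoglobin genes have near-identical copies. Of 24 dermal papilla markers, 5 were higher and 13 lower in the papilla (median log2 ratio -1.08, percentile 0.0100), so this list was on balance higher in the pulp.

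Wnt ligands and agonists were lower in 7 of 8 (1 higher, median log2 ratio -2.62, percentile 0.0100): WNT5A by 10.7-fold (7.31 to 16.2) and WNT11 by 16.8-fold (5.55 to 82.9), while RSPO3 was 2.74-fold (2.11 to 3.58) higher. Proliferation genes were lower in 14 of 31 (median log2 ratio -0.96, percentile 0), and MKI67 was 1.80-fold (1.36 to 2.4) lower. Higher in the papilla were 10 of 20 immediate early and stress genes (2 lower, median log2 ratio 1.04, percentile 99.98), led by HSPB1 at 13.8-fold (11.6 to 16.4), and 10 of 24 hypoxia and glycolysis genes (2 lower, median log2 ratio 0.80, percentile 99.95), led by the glycolytic enzyme TPI1 at 5.04-fold (4.15 to 6.14). Epithelial markers were higher in 7 of 15 (2 lower, median log2 ratio 0.84, percentile 99.7), CDH1 by 3.94-fold (2.64 to 6.01), and basement membrane genes in 6 of 17 (5 lower, median log2 ratio 0.56, percentile 98.2). The skeletal muscle list rested on 4 genes (median log2 ratio 1.80, percentile 99.7).

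In total 980 records were at least 2-fold higher and 1271 lower in the papilla than in the pulp, of 6667, against 21.0 from counting error alone. The proliferation, epithelium, endothelium, erythroid and basement membrane lists no longer stood apart at a minimum of 200 reads, nor the erythroid and skeletal muscle lists with no filter, where the skeletal muscle median turned to -0.14.

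The pulp was compared with the epithelium as the remaining pair of growing tissues, both from deeper libraries of the same table format. PENK, the precursor of the enkephalin peptides, was 566-fold (424 to 773) higher in the pulp, CRABP1 645-fold (351 to 1346), CXCL14 263-fold (198 to 359) and SFRP2 706-fold (195 to 5830.5). The interferon-induced OASL and the growth factor IGF2, with 2592 and 1341 reads in the pulp, were unlisted in the epithelium and at least 619.9-fold and at least 321-fold higher. Lower in the pulp were CSTA by 4284-fold (2505 to 8046), FABP5 by 1608-fold (1180.3 to 2250.4), LY6EL by 924-fold (395 to 2847), PERPB (LOC421682) by 320.1-fold (232 to 455) and carboxypeptidase M (CPM) by 227-fold (119 to 497). The tight junction gene CLDN1, with 1383 reads in the epithelium, was unlisted in the pulp and at least 643-fold lower. LEF1 did not differ beyond counting error (ratio 0.917, 0.748 to 1.12), and with the deposited RPM values its log2 ratio turned from -0.12 to 0.43.

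Mesenchymal, vascular and immune lists were higher in the pulp. Fibroblast and matrix genes were higher in 24 of 26 (2 lower, median log2 ratio 5.08, percentile 100), with COL6A1 at 157-fold; dermal papilla markers in 19 of 22 (median log2 ratio 4.07, percentile 100, or 4.38 with unlisted members at their bound). Endothelial markers were higher in 19 of 19 (median log2 ratio 3.28, percentile 100) and leukocyte markers in 23 of 23 (median log2 ratio 3.54, percentile 100), the MHC class II gene BLB2, which has similar copies, by 324-fold (170.4 to 709). Retinoic acid genes were higher in 5 of 8 (median log2 ratio 3.99, percentile 100), Wnt inhibitors in 9 of 13 (3 lower, median log2 ratio 3.16, percentile 100), Wnt ligands in 6 of 9 (2 lower, median log2 ratio 2.36, percentile 99.4), BMP and TGF-beta genes in 12 of 22 (2 lower, median log2 ratio 1.17, percentile 99.6) and homeobox and T-box genes in 9 of 18 (3 lower, median log2 ratio 1.55, percentile 99.8). The smooth muscle list was higher in 8 of 12 (2 lower, median log2 ratio 2.06, percentile 99.9), led by PDGFRB at 56.1-fold (27.0 to 140.1). Basement membrane (2.96), matrix remodelling (1.79) and wound and inflammation genes (1.86) also had median log2 ratios above the random lists.

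Epithelial markers were lower in the pulp in 16 of 20 (1 higher, median log2 ratio -3.09, percentile 0, or -3.62 with unlisted members at their bound), feather cornification genes in 8 of 10 (1 higher, median log2 ratio -4.05, percentile 0, or -4.86 at the bound) and melanocyte markers in 7 of 8 (1 higher, median log2 ratio -3.27, percentile 0, or -3.66 at the bound). The envoplakin gene EVPL, a cornified envelope protein, was 66.7-fold (41.4 to 115) lower and TGM3, which crosslinks that envelope, was at least 139-fold lower. Ribosomal protein (-1.53), hypoxia and glycolysis (-0.70) and oxidative phosphorylation genes (-0.62) had median log2 ratios below the random lists. Proliferation genes did not stand apart (median log2 ratio 0.10, percentile 57.6): TOP2A was 2.10-fold (1.71 to 2.58) lower in the pulp and MKI67 1.92-fold (1.47 to 2.53) higher. In total 1832 records were at least 2-fold higher and 1398 lower, of 6851, against 13.9 from counting alone. With the deposited RPM values the median of all records was 0.61 in place of 0.08 and the split became 2625 higher and 761 lower. At a minimum of 200 reads the smooth muscle, homeobox, oxidative phosphorylation and wound lists no longer stood apart, nor the BMP list with no filter.

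Records at least 4-fold higher in the growth-phase papilla than in both epithelium and pulp numbered 196, and 175 of them carried a symbol. They included 10 of the 15 smooth muscle list members and 3 of the 34 dermal papilla list members found in the tables. Fewer members had at least 20 reads in either library: 14 and 24 for papilla and pulp, 13 and 18 for papilla and epithelium. The 12 enriched records with the largest smaller ratio were WFIKKN2, MUSTN1, DES, ACTG2, MYLK, TPPP3, HSPB7, SCP2, TMEM255B, MYH11, LRRN6A and DMN. Of these 12, MUSTN1, DES, MYLK, MYH11 and LRRN6A were also at least 4-fold lower in epithelium and pulp than in each of the other 4 libraries, as were 27 of the 196. ACTG2, a smooth muscle actin, was 182-fold (150.2 to 224) higher than in the epithelium and 101-fold (89.1 to 114) higher than in the pulp, and MYLK, the kinase of myosin light chain, 119-fold (102 to 141) and 72.4-fold (65.0 to 80.9). Reads of the actin genes are uncertain, since the family is highly similar. In the resting papilla 91 of the 196 records were at least 2-fold lower than in the growth-phase papilla and 2 were higher; in the day 4 follicle 143 were lower and 0 higher. The list was chosen for high values in the growth-phase papilla, which favours lower values elsewhere. A list chosen in the same way in the resting papilla held 145 records, of which 33 were higher and 29 lower at rest than in growth. That list and a version requiring a value 2-fold above the day 4 follicle (143 records) were added after seeing the data.

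The growth-phase papilla was then compared with the resting papilla, the contrast named in the series' design, within libraries of like depth and table format. Higher in growth were the myosin light chain MYL4 by 18.5-fold (15.1 to 22.9), ACTG2 by 7.02-fold (6.72 to 7.33), MYL9 by 4.87-fold (4.75 to 5.0) and DES by 2.64-fold (2.37 to 2.94). WFIKKN2 was 7.38-fold (6.45 to 8.47) higher, the secreted growth factor pleiotrophin (PTN) 8.13-fold (5.99 to 11.3) and SCP2 (LOC396550) 8.10-fold (6.1 to 10.9). HBA1, a haemoglobin gene of red blood cells with near-identical copies, was 8.29-fold (6.02 to 11.7) higher. Higher at rest were the keratin KRT10 (LOC771977) by 24.6-fold (14.7 to 44.4), CSTA by 22.1-fold (13.4 to 39.0), EVPL by 18.7-fold (11.7 to 32.0), FABP5 by 16.5-fold (13.5 to 20.2), PERPB by 9.15-fold (7.22 to 11.7) and CDH1 by 2.80-fold (2.18 to 3.64). The lipocalin P20K was 7.99-fold (5.95 to 10.9) lower in growth.

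Among the signalling genes chosen for every comparison, the Wnt inhibitors split by member. DKK2 was 1.65-fold (1.47 to 1.85) and FRZB 1.52-fold (1.43 to 1.61) higher in growth, SFRP2 had a ratio of 1.06 (0.910 to 1.25), and WIF1 was 3.73-fold (2.05 to 7.27) lower; the list did not stand apart, with 2 higher and 3 lower of 11 (median log2 ratio 0.09, percentile 59.9). BMP4 was 1.90-fold (1.70 to 2.12) higher in growth. Its antagonist NOG, 23 against 35 reads, and the Wnt target AXIN2, 5 against 9 reads, did not differ beyond counting error, whereas LEF1 was 3.73-fold (1.36 to 12.7) lower in growth from 5 against 20 reads. MKI67 was 1.75-fold (1.17 to 2.65) higher and TOP2A had a ratio of 1.32 (0.866 to 2.02). COL1A1 was 2.08-fold (1.45 to 3.0) higher.

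The epithelium list was lower in growth in 11 of 18 members (median log2 ratio -1.48, percentile 0) and feather cornification in 5 of 6 (median log2 ratio -2.39, percentile 0). The smooth muscle list was higher in 10 of 13 (median log2 ratio 1.46, percentile 100) and the erythroid list in 3 of 5 (median log2 ratio 1.44, percentile 99.9). Smaller shifts above the random lists were seen for the endothelium (0.47), basement membrane (0.65), fibroblast and matrix (0.41), retinoic acid (0.93) and oxidative phosphorylation lists (0.32), given as median log2 ratios; the basement membrane collagen COL4A1 was 3.29-fold (3.14 to 3.45) higher. Below the random lists were the ribosomal protein (-0.44), growth arrest (-0.47), matrix remodelling (-0.46) and BMP and TGF-beta lists (-0.39), with the activin subunit INHBA 4.06-fold (2.56 to 6.70) lower and BMP7 3.39-fold (2.76 to 4.20) higher. The skeletal muscle list rested on 3 genes (median log2 ratio 1.39, percentile 99.3). Dermal papilla markers did not stand apart: 3 of 21 were higher, 4 lower and 14 within 2-fold (median log2 ratio 0.09, percentile 63.7). This list shares DKK2 and WIF1 with the Wnt inhibitors and NOG with the BMP and TGF-beta list, so these lists are not separate results. Proliferation genes were within 2-fold in 22 of 25 (median log2 ratio 0.26, percentile 96.0).

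In total 558 records were at least 2-fold higher and 475 lower in growth than at rest, of 5957, against 21.6 from counting error alone. With the deposited RPM values the median of all records was -0.13 in place of -0.02 and the split turned to 441 higher and 627 lower; it turned as well with scaling without the 100 most abundant records (464 and 581) and at 4-fold (52 and 82). The BMP, growth arrest, matrix remodelling, retinoic acid and basement membrane lists lost their standing with the mean in place of the median, the endothelium list with a pseudocount of 0.1, the oxidative phosphorylation and fibroblast lists at 200 reads and the skeletal muscle list with no filter; the BMP median turned to 0.39 at 200 reads.

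Regeneration was compared with the resting phase through the day 2 follicle and the resting papilla. These differ in tissue as well as in phase, follicle against dermal papilla, so each value contains both differences. Higher in the day 2 follicle were the interferon-induced OASL by 110.0-fold (55.6 to 256), IFIT5 (LOC423790) by 40.8-fold (29.2 to 58.8), MX by 28.8-fold (15.9 to 58.3) and ISG12-2 by 15.5-fold (10.7 to 23.2). The gelatinase MMP9, with 222 reads on day 2, was unlisted at rest and at least 73.3-fold higher, and LTF, a transferrin-family protein, was 23.7-fold (16.3 to 36.0) higher. Lower in the day 2 follicle were DES by 8.07-fold (6.15 to 10.8), MUSTN1 by 7.79-fold (7.20 to 8.44), HSPB7 by 7.16-fold (5.52 to 9.41), WFIKKN2 by 12.5-fold (7.90 to 20.8), KLHDC8B by 11.6-fold (7.27 to 19.7) and the small GTPase RRAD by 6.89-fold (5.52 to 8.68). DKK2 was 3.45-fold (2.87 to 4.17) lower and WIF1 11.3-fold (4.57 to 36.2) lower, and NOG, with 35 reads at rest, was unlisted and at least 11.8-fold lower; the Wnt inhibitor list did not stand apart (median log2 ratio -0.31, percentile 12.7).

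Between these different tissues, leukocyte markers were higher in the day 2 follicle in 11 of 14 (median log2 ratio 1.81, percentile 100), C1QB by 11.5-fold (7.42 to 18.6), and wound and inflammation genes in 10 of 16 (median log2 ratio 1.77, percentile 100), the decoy interleukin receptor IL1R2 by 7.78-fold (4.93 to 12.9). Erythroid markers were higher in 3 of 5 (median log2 ratio 2.05, percentile 100) and endothelial markers in 6 of 15 (median log2 ratio 0.65, percentile 99.97). Cartilage and tendon genes were higher in 4 of 7 (1 lower, median log2 ratio 1.72, percentile 99.9), COMP by 4.71-fold (4.44 to 5.0) and osteopontin (SPP1) by 7.73-fold (5.42 to 11.3). The matrix remodelling list did not stand apart (median log2 ratio 0.29, percentile 96.0), although MMP1 and MMP10 were unlisted at rest and at least 29.4-fold and at least 20.8-fold higher on day 2. The smooth muscle list was lower in 8 of 12 (1 higher, median log2 ratio -1.48, percentile 0), MYH11 by 6.38-fold (6.03 to 6.76), and the skeletal muscle list rested on 3 genes (median log2 ratio -2.38, percentile 0). Feather cornification (0.53) and fibroblast and matrix genes (0.21) had median log2 ratios above and oxidative phosphorylation genes (-0.30) below the random lists. In total 424 records were at least 2-fold higher and 361 lower in the day 2 follicle than in the resting papilla, of 6013, against 18.8 from counting alone; at 4-fold the split was 104 and 39. At 200 reads the endothelium, cornification, fibroblast and oxidative phosphorylation lists no longer stood apart, nor the cartilage and skeletal muscle lists with no filter.

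Within regeneration, the day 4 follicle was compared with the day 2 follicle, on the assumption that both were the same tissue. Lower on day 4 were the interferon-induced OASL by 28.0-fold (19.9 to 40.7), MX by 24.5-fold (14.4 to 45.3), ISG12-2 by 16.7-fold (11.6 to 25.1) and IFIT5 by 15.6-fold (12.7 to 19.3). P20K was 10.9-fold (9.46 to 12.6) lower and glutamine synthetase (GLUL) 12.3-fold (8.22 to 19.1) lower. Higher on day 4 were the corticotropin-releasing hormone binding protein CRHBP by 7.38-fold (5.46 to 10.2), the glutathione transferase GSTA3 by 4.73-fold (3.67 to 6.16), FABP5 by 3.47-fold (3.28 to 3.69), the ubiquitin ligase RNF122 (LOC426922) by 3.36-fold (2.80 to 4.05), the transcription factor SNAI2 by 3.08-fold (2.52 to 3.78) and the mitochondrial import protein CHCHD4 by 2.90-fold (2.19 to 3.87). LEF1 was 3.52-fold (1.88 to 7.06) higher and WNT6 10.9-fold (4.76 to 30.7) higher on day 4, while DKK2 was 1.95-fold (1.48 to 2.58) and FRZB 1.42-fold (1.31 to 1.54) lower. The Wnt ligand list did not stand apart, with 1 higher and 2 lower of 5 (median log2 ratio 0.53, percentile 97.1), nor did the Wnt inhibitors, with 9 of 9 within 2-fold (median log2 ratio -0.10, percentile 19.5).

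Proliferation genes were higher on day 4 in 12 of 28 and lower in 0 (median log2 ratio 0.90, percentile 100): TOP2A by 3.12-fold (1.87 to 5.44), MKI67 by 2.86-fold (1.89 to 4.44) and the replication licensing factor MCM3 by 4.66-fold (2.48 to 9.52). Wound and inflammation genes were lower in 5 of 20 and higher in 2 (median log2 ratio -0.45, percentile 0.300), IL1R2 by 6.1-fold (4.09 to 9.39). Matrix remodelling genes were lower in 4 of 21 (median log2 ratio -0.35, percentile 0.75), MMP9 by 2.77-fold (2.15 to 3.59) and MMP1 by 3.67-fold (2.35 to 5.92), and cartilage and tendon genes in 3 of 6 (median log2 ratio -0.90, percentile 0.50), COMP by 6.23-fold (5.85 to 6.65). Other lists stood apart with small medians: fibroblast and matrix (-0.32) and dermal papilla (-0.27) below the random lists, and epithelium (0.29), ribosomal protein (0.26) and immediate early genes (0.34) above them, all on the log2 scale. Leukocyte (median log2 ratio -0.18, percentile 10.8), endothelial (median log2 ratio -0.13, percentile 15.2) and smooth muscle markers (median log2 ratio -0.07, percentile 18.4) did not stand apart. In total 228 records were at least 2-fold higher and 232 lower, of 6048, against 17.0 from counting alone; at a minimum of 200 reads the split was 30 and 54, and it turned to 269 and 213 with the deposited RPM values and to 244 and 224 with scaling without the 100 most abundant records. The dermal papilla, epithelium and immediate early lists lost their standing at 200 reads, and the cartilage list with no filter.

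**Figure D2:**
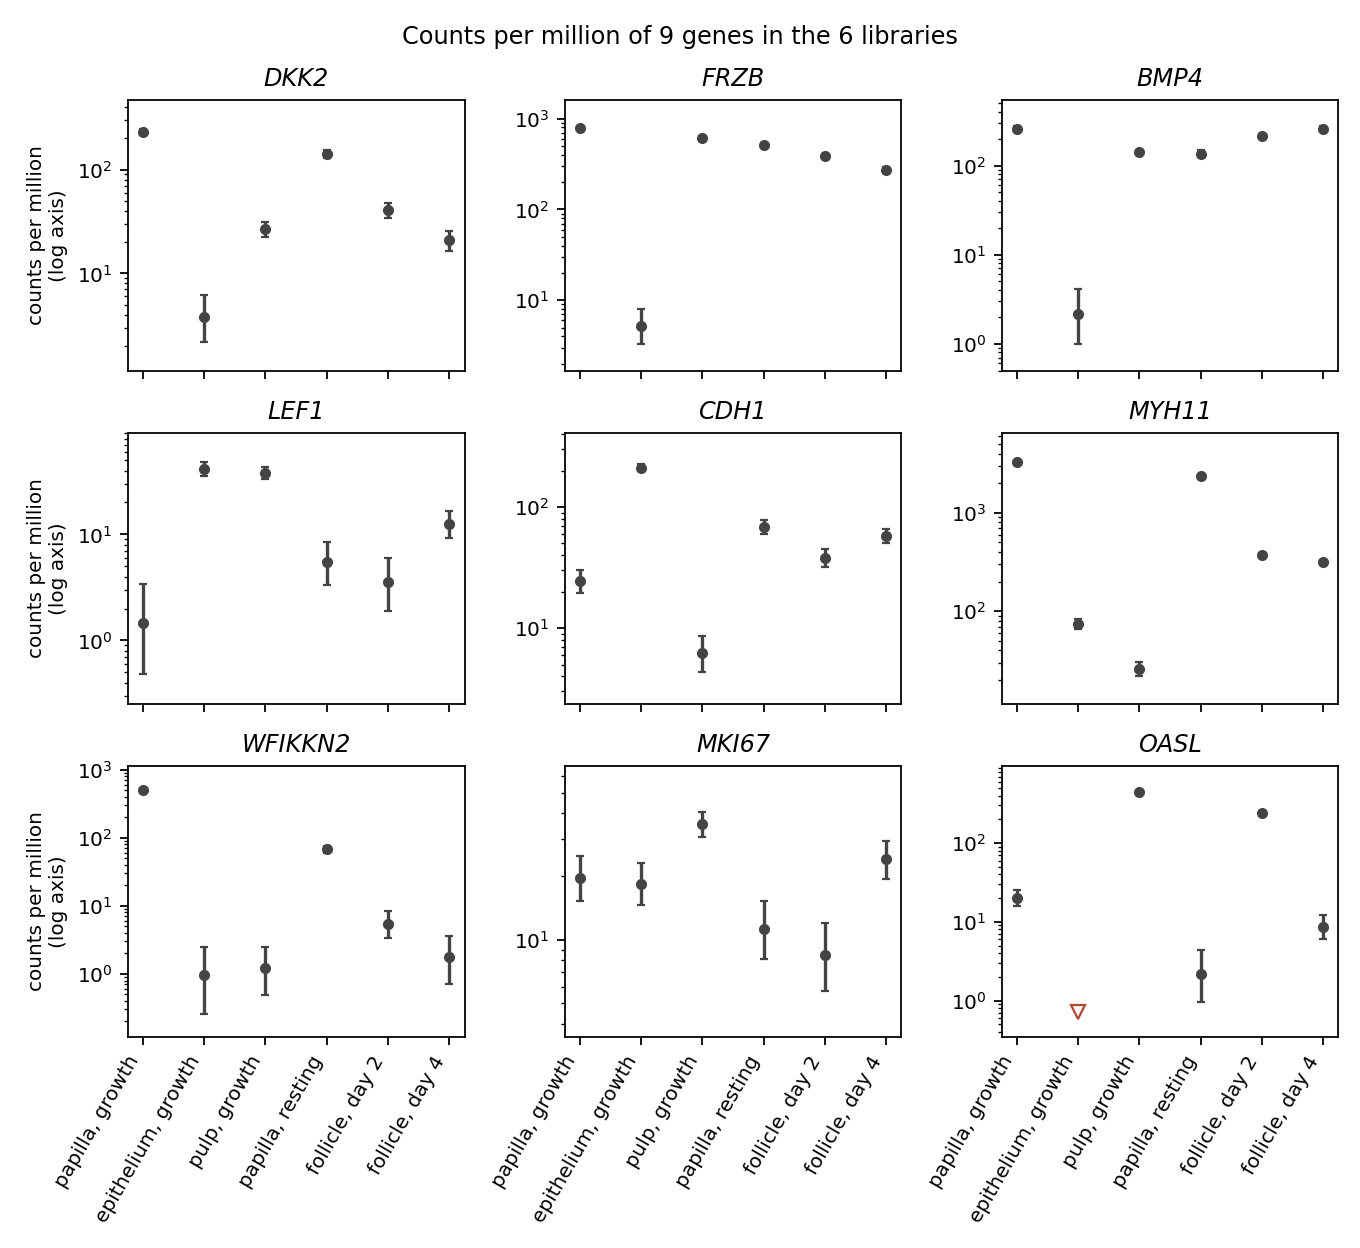
TMM-scaled read abundance (CPM, log axis) of 9 genes in the 6 libraries; points are single libraries, bars are exact 95% Poisson intervals for counting error, and the open triangle marks a library that does not list the gene, drawn at the value of 3 counts. DKK2 runs from 230.4 in the growth-phase papilla to 3.84 in the epithelium, and OASL is high in the pulp and the day 2 follicle.

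Lists for Schwann cells and nerve, adipocytes, Wnt receptors and targets, FGF, hedgehog with Notch and EDA, adhesion and guidance, and housekeeping genes stood apart in none of the comparisons in which at least 3 members were measured. The nerve list reached that number between the day 2 follicle and the resting papilla alone, different tissues, with a median log2 ratio of -1.03. Between growth-phase papilla and epithelium the medians were 2.68 for adipocytes (percentile 97.4), 0.56 for Wnt receptors and targets, 0.60 for FGF, -0.07 for hedgehog with Notch and EDA, 0.46 for adhesion and guidance and -0.33 for housekeeping genes; between the papillae of both phases the housekeeping median was -0.03.

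**Figure D3:**
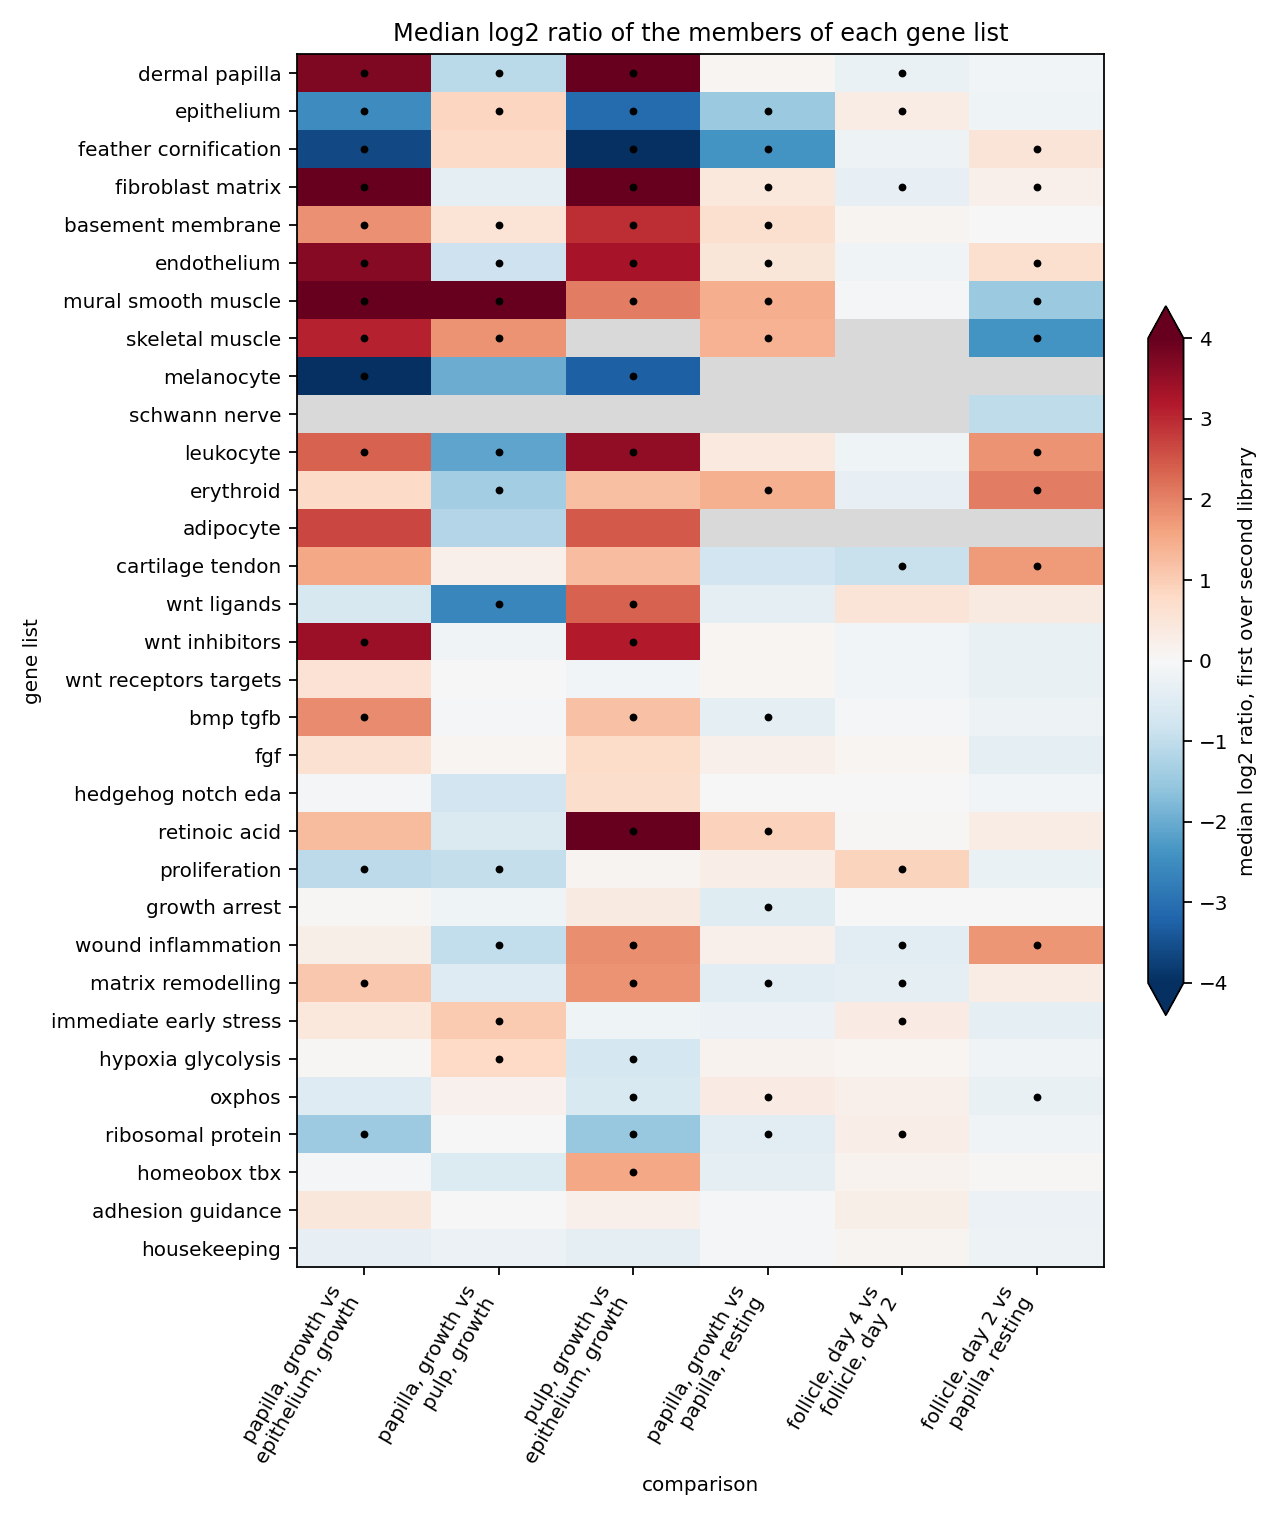
Median log2 ratio of the measured members of each of the 32 gene lists (vertical axis) in each comparison (horizontal axis); red is higher and blue lower in the first library, colours saturate at 4, and grey marks fewer than 3 measured members. A black point marks a median outside the central 95% of 10000 matched random lists, which held for 80 of 179 list comparisons. For randomly drawn genes 9 would be reached by chance. Lists share members and comparisons share libraries, so 9 is only a reference number.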

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

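With a pseudocount of 5 the records 2-fold apart numbered 552 between growth and resting papilla, 179 between day 4 and day 2, and 418 between day 2 follicle and resting papilla, which are different tissues, and the enriched list held 101, since a larger pseudocount shrinks ratios of low counts. With no filter these comparisons gave 1698, 1070 and 1475, as records with few counts entered. At a minimum of 200 reads fewer records were compared, and the counts were 1000 for papilla against epithelium (459 higher, 541 lower, a turn), 801 for papilla against pulp, 1344 for pulp against epithelium, 266 for growth against rest, 84 for day 4 against day 2, 209 for day 2 against rest and 84 enriched. The 4-fold rule gave 1349 (856 higher, 493 lower), 711 (301, 410), 1476 (1013, 463), 134 (52, 82), 42 (18, 24) and 143 (104, 39) in the same order of comparisons, so that growth against rest turned to more lower than higher. Scalings, including the RPM values added after the data were seen, a pseudocount of 0.1 and summing records per symbol left each of these totals within 1.5 times. The splits moved further with the RPM values: lower records went from 1443 to 861 for papilla against epithelium and from 1398 to 761 for pulp against epithelium. Of the 80 list medians that stood apart, 33 lost this under at least 1 of the 10 alternatives run for lists and 47 did not, 7 of which were not run at 200 reads; 24 others stood apart under some alternative. The skeletal muscle median between papilla and pulp turned to -0.14 with no filter, and the BMP and TGF-beta median between growth and rest to 0.39 at 200 reads; the cause was not tested. Of 796 ratios of named genes and list members with at least 20 reads, 436 of them also run at 200 reads, 0 of those at least 2-fold apart changed direction and 6 smaller ones did. By more than counting error, 107 moved with the RPM values, 66 with a pseudocount of 5, 30 with 0.1, 23 without the 100 most abundant records, and 6 and 5 with the other scalings. With unlisted members at a bound of 3 counts, 15 of 179 list medians moved, by at most 0.81, with 0 changes of sign. Each group had 1 library, so none could be left out, and spread between birds was not measured.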

Other observations

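All tests of explanations in this part, and the interferon gene list, were chosen after the results were seen. Interferon response genes were higher in the pulp and the day 2 follicle than in the libraries they were compared with. In the day 2 follicle 18 of 22 measured members were at least 2-fold higher than in the resting papilla, a different tissue, and 0 lower (median log2 ratio 2.09, percentile 100). On day 4, 16 of 22 were lower than on day 2 and 0 higher (median log2 ratio -1.28, percentile 0). In the pulp 22 of 24 were higher than in the epithelium and 2 lower (median log2 ratio 3.45, percentile 100), and 20 of 24 were lower in the growth-phase papilla than in the pulp (median log2 ratio -2.14, percentile 0). Between growth-phase papilla and epithelium 10 of 16 were higher (median log2 ratio 1.84, percentile 99.97), and between the papillae of both phases the list did not stand apart (median log2 ratio 0.19, percentile 85.5). Leukocyte markers were higher with it in the pulp against the epithelium (23 of 23, median 3.54) and on day 2 against rest (11 of 14, 1.81) and lower in the papilla against the pulp (21 of 23, -2.11), but did not stand apart between day 4 and day 2 (-0.18). The interferon list took 0.599% of listed reads in the pulp and 0.449% on day 2, against 0.0187% in the epithelium and 0.0699% in the resting papilla. Because the list was written from genes seen in these libraries, its direction is not independent evidence; IRF8 is also in the leukocyte list and B2M in the housekeeping list.

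Some of the most abundant epithelial records carried no gene symbol and their reads are uncertain, since feather keratin genes have near-identical copies. LOC426911 had 245216 reads in the epithelium, 56 in the growth-phase papilla, 24 in the pulp, 1225 in the resting papilla, 1784 on day 2 and 9695 on day 4. LOC772080 had 34794 in the epithelium, 80 and 4974 in the growth-phase and resting papilla, 7326 on day 2 and 11032 on day 4. LOC420043 had more reads in the resting papilla (3105) than in the epithelium (1946). ARIH1 was among the most abundant records of the other tissues, with 74792 reads in the pulp, 29408 in the resting papilla and 22455 in the growth-phase papilla.

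Epithelial genes were higher in the resting than in the growth-phase papilla. A single share of carried-over tissue with the composition of the growth-phase epithelium library would give like implied shares. The shares implied by single records differed widely, but spread between libraries was not measured. The 11 list members used were at least 4-fold higher in the epithelium than in the growth-phase papilla, chosen without the resting library. They would need a median share of 23.7% (3.98% to 68.8%). Of the 10 most abundant epithelium-specific records outside the list, 9 implied under 1/2 of that (-0.265% to 16.1%, median 3.63%), and LOC426911 implied 0.545%. The 2 sets are not like for like: epithelium-specific records had a log2 ratio of at least 4 over both papilla and pulp, and several are unnamed with uncertain reads. The 10 were also ranked by their epithelium value, by which the share is divided, and this favours low shares. The comparison of the 2 sets therefore cannot decide on carried-over tissue. List members that met this rule implied 3.98% (GRHL3), 7.28% (PERP), 18.6% (TACSTD1) and 28.4% (CLDN1). Over the 50 records that met it, the median was 6.2% and the 90th percentile 20.4%. Of the 11 list members higher at rest, 3 (LAMA3, FERMT1 and KRT6A) were also higher there than in the epithelium. The ratios were 8.11-fold (6.60 to 10.1), 1.87-fold (1.23 to 2.88) and 2.87-fold (2.34 to 3.54). LAMA3, however, was lower in the epithelium (24.9 CPM) than in the growth-phase papilla (58.3 CPM), so it does not mark epithelium here. KRT6A is a keratin, whose reads are uncertain. A mixture of the growth-phase papilla and epithelium as sampled would not lie above both libraries. The intervals cover counting error only, so spread between libraries could still account for such ratios. These values cannot exclude a part of the growth-phase epithelium with another composition, nor a share of a few percent. Scaling is argued against, as the list median nearest to 0 over 5 scalings was -1.43. Epithelium of the resting follicle, which no library here sampled alone, may have been taken with the papilla, or papilla cells may differ between phases. Both stay open and untested, and carried-over growth-phase epithelium, of the sampled or another composition, is not excluded.

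Smooth muscle genes were higher in the growth-phase papilla than in the pulp, with a list median of 4.40. More blood vessel with its endothelium in the papilla library is argued against, since the endothelium list median was -0.83, with 13 of 19 members within 2-fold. That list lost its standing at a minimum of 200 reads and with the mean of members. Endothelial genes do not measure the muscle of vessel walls, so more of that muscle alone stays open. The smooth muscle list took 6.84% of listed reads in the growth-phase papilla, 2.16% in the resting papilla and 0.239% in the pulp. These shares leave out CSRP1, which is not on the list and had 72939 reads in the growth-phase papilla. The muscles that move feathers could have been taken with the papilla, and papilla cells that use these genes would give the same values; these cannot be told apart without a library of feather muscle. Its most abundant members there were MYL9 with 33336 reads and ACTG2 with 15302; DES is also in the skeletal muscle list and PDGFRB in the fibroblast and matrix list, and for DES, MYLK and MYH11 the split between sets of tables stays open too.

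The epithelium and pulp libraries stood apart from the other 4 in 59 records, of which 29 were at least 4-fold higher and 30 lower than in every other library; the growth-phase papilla with pulp gave 35, the next highest number. CHCHD2 had 1130 and 1593 reads in these libraries and 10 to 25 in the others, and TMEM63C was unlisted in both and had 47 to 90 reads elsewhere. Of the 59, 27 were papilla-enriched records, 5 of them among the top 12 (MUSTN1, DES, MYLK, MYH11 and LRRN6A). Any record in the lower group meets the 4-fold part of the enriched rule by definition, so this overlap is no separate result. After every library was thinned to a total of 3269376, 58 of the 59 records stayed apart. This was nearly fixed in advance, since the records were chosen on scaled ratios, which thinning leaves almost unchanged. It therefore cannot decide whether differences that go with depth account for these records. Birds or processing shared by these tables may account for them, since 17 records were unlisted throughout one set, but the tissues are confounded with the tables, so this cannot be told apart from tissue.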
